A study of Drosophila melanogaster with 16 samples.

How the data were processed

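RNA of 4 kinds of Drosophila eye-antennal disc tumours (RasV12 scrib, RafGOF scrib, RasV12 baz and RasV12 cdc42) was compared with wild-type reference RNA on 16 custom 2-colour arrays, 4 per genotype. Per the labels' protocols, total RNA was taken with TRIzol from about 30 to 40 discs, and amplified and labelled with random hexamers. Tumour RNA was labelled with Cy3 and the reference with Cy5, except on the dye-swapped arrays, which were RasV12 scrib replicates 1 and 3 and RasV12 cdc42 replicates 1 and 2. RafGOF scrib and RasV12 baz had no swapped array. Tumour RNA is channel 1 of every array per the labels.

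The authors deposited 1 table of log2 ratios, with 1 row per feature and 1 column per array. How spots were scanned, background-corrected, normalised, filtered or averaged is not given in the sources used here. The log base was inferred: of 409 values other than 0 that were repeated at least 3 times on an array, 36.7% equalled the log2 of a ratio of whole numbers up to 9 within 1e-05, and 0% equalled such a natural or decimal logarithm. The columns were not centred, with medians from -0.12 to 0.48, so the zero of each array is the authors' own. Arrays of opposite dye orientation correlated above 0, so the deposited values were taken as already turned the same way and no sign was changed. That tumour over reference is the direction is likely from the channel order and is not stated. Signal and background levels were not used here, so the precision comes from the spread between arrays alone.

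Features carry FlyBase-style identifiers, apart from a few given by name. They were matched to the symbols and synonyms of an NCBI gene table of the Release 6 assembly, which gave 1 symbol to 71 identifiers, several symbols to 1 and none to 11124. No other name was assigned. The array's genome build is not given, so no coordinates are printed. Of 406 genes in 26 fixed lists, 2 were matched (Lsp2 and LanA), which is fewer than the 3 members a list test needed, so no list was tested. The engineered genes could not be checked because none of them was matched to a feature by name. They may be among the features given below by identifier alone.

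Computation used R 4.3.3 and limma 3.58.1, and figures used Python 3.11.15 with matplotlib 3.10.9. RafGOF scrib replicates 1 and 2, identical in all but 552 features and differing by over 0.1 in 56, were averaged into 1 replicate. A linear model with a mean per genotype and a dye term was fitted to all 15 replicates, followed by empirical Bayes moderation. A genotype's mean tested against 0 gave its comparison with wild-type, in which wild-type RNA enters only as the reference. The control's own spread is left out where arrays share 1 reference RNA, which the labels do not state. Contrasts gave the comparisons between genotypes, and an F-test over the 4 genotypes gave the genes that differ among them. P-values were adjusted by Benjamini-Hochberg within each comparison, at a threshold of 0.05, and are two-sided. No gene had a dye effect past the threshold (limma, lowest adjusted p = 0.145), and 1156 had an unadjusted p under 0.05.

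Genes named in the text had a symbol, passed the threshold and had the same sign on every replicate, or no overlap between genotypes. Up to 10 per direction were taken by size of the change. Named genes that passed the threshold without that last condition are given separately. For features without a symbol, at most 2 identifiers per direction are given for each comparison. Values are log2 changes ± SE of the fit, and folds are 2 to the power of their size. RafGOF scrib and RasV12 baz had no swapped array. Their fitted values include a dye correction estimated from the genotypes with swapped arrays, and can differ from the replicate means. In RasV12 cdc42 dye coincides with the pairs of replicates that resembled each other. The correction therefore cannot be told apart there from a difference between these pairs. It may carry such a difference into every comparison of RafGOF scrib and RasV12 baz, and is not known to be dye alone.

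The fit was tested on simulated data with the real design and 11196 genes, 200 of them changed. In RasV12 scrib against wild-type it recovered 87% of genes changed by a log2 value of 1 and 100% of those changed by 2, with 12 false calls. In RasV12 cdc42 against RasV12 baz it recovered 15% and 92%, with 7 false calls. The simulated errors were independent between arrays, whereas real replicates 1-2 and 3-4 resembled each other. These recoveries and false calls may therefore be too favourable for the real arrays. Counts were also taken from other splits of the arrays, and from splits that keep replicates 1-2 and 3-4 balanced or together, which were chosen after the result was seen. The sharing of changes between genotypes was set beside 20 simulations of unchanged tumours, whose tumour errors were also independent between arrays.

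The results were also fitted under other settings. Those set before the data were examined were a fit without the dye term, the arrays with tumour RNA in Cy3 alone, the replicate number as a block, centring of arrays on their median, scaling to an equal median absolute deviation, quantile normalization, robust empirical Bayes, array weights, the compared genotypes alone, a 2-fold limit, and each replicate left out in turn. The restricted maximum likelihood estimate of array weights did not converge, so they were estimated gene by gene and without blocks of replicates. Filters on missing values and rules for several probes of a gene had nothing to act on. Settings added after the data were seen were the RafGOF scrib pair kept separate, replicates 1-2 and 3-4 of each genotype as random blocks, these replicate groups as a fixed block over all genotypes, and a fit without the arrays in doubt.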

Results

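Gene expression was measured in tumours that arose from mutant clones in the eye-antennal imaginal discs of Drosophila larvae, the epithelial sacs that form the adult eye and antenna. Tumours of 4 genotypes were taken at day 10 and set against wild-type discs of day 5 to 6, both from larvae kept at 25 °C. Age and tumour thus differed together in every comparison with wild-type and cannot be told apart there. Of the 4 genotypes, 3 carried an activated Ras (RasV12) together with loss of scrib, baz or cdc42, and 1 carried a gain-of-function Raf (RafGOF) together with loss of scrib. The products of scrib, baz and cdc42 act in epithelial cell polarity, and Raf is a kinase directly downstream of Ras. The comparisons address how the expression of each tumour differed from wild-type discs and how tumours of distinct genetic origin differed from one another. Each genotype had 4 custom arrays on which tumour RNA was hybridised with wild-type reference RNA in a pair of dyes. Each array gave a log2 ratio for 11196 features, with no missing value.

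RafGOF scrib replicates 1 and 2 held the same value for 95.07% of the features, against at most 0.14% for any other pair of arrays. Their closeness is beyond that of separate samples here (highest r of any other pair 0.81), so their mean was counted as 1 replicate and RafGOF scrib had n = 3. The other genotypes had n = 4, which left 15 replicates in all, and these numbers of arrays limit the precision of every value. The labels call the arrays biological replicates.

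A positive log2 ratio is read here as higher in the tumour. This direction is likely but not stated in the sources used here. Its only basis is that the labels give the tumour as channel 1 of every array. Dye-swapped arrays did not run against the others, which shows that all arrays are turned the same way but not which way. With reference over tumour every higher and lower below would change places at the same size, such as 1309 higher and 1160 lower genes in RasV12 scrib. RasV12 scrib replicates 1 and 2, labelled with opposite dyes, correlated at r = 0.77 across genes, and the lowest r of any pair of arrays was 0.07. The median log2 value over all features was 0.05 for RasV12 scrib, 0.24 for RafGOF scrib, 0.15 for RasV12 baz and 0.14 for RasV12 cdc42. Where centring or another scaling of the arrays changed the balance of higher and lower genes, that split is given with the count.

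Across genes, which are not independent replicates, arrays of 1 genotype correlated with a median r of 0.47 (range 0.20 to 0.81, 21 pairs) and arrays of different genotypes with a median of 0.38 (range 0.07 to 0.71, 84 pairs). For 13 of the 15 replicates the closest array had the same genotype. The exceptions were RafGOF scrib replicate 1, closest to RasV12 scrib replicate 1 (r = 0.64), and RasV12 baz replicate 4, closest to RasV12 cdc42 replicate 4 (r = 0.71). Within RasV12 scrib and within RasV12 cdc42, replicates 1 and 2 lay close together and so did replicates 3 and 4. Mean r was 0.79 within these pairs and 0.48 across them in RasV12 scrib, and 0.81 and 0.33 in RasV12 cdc42.

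**Figure D1:**
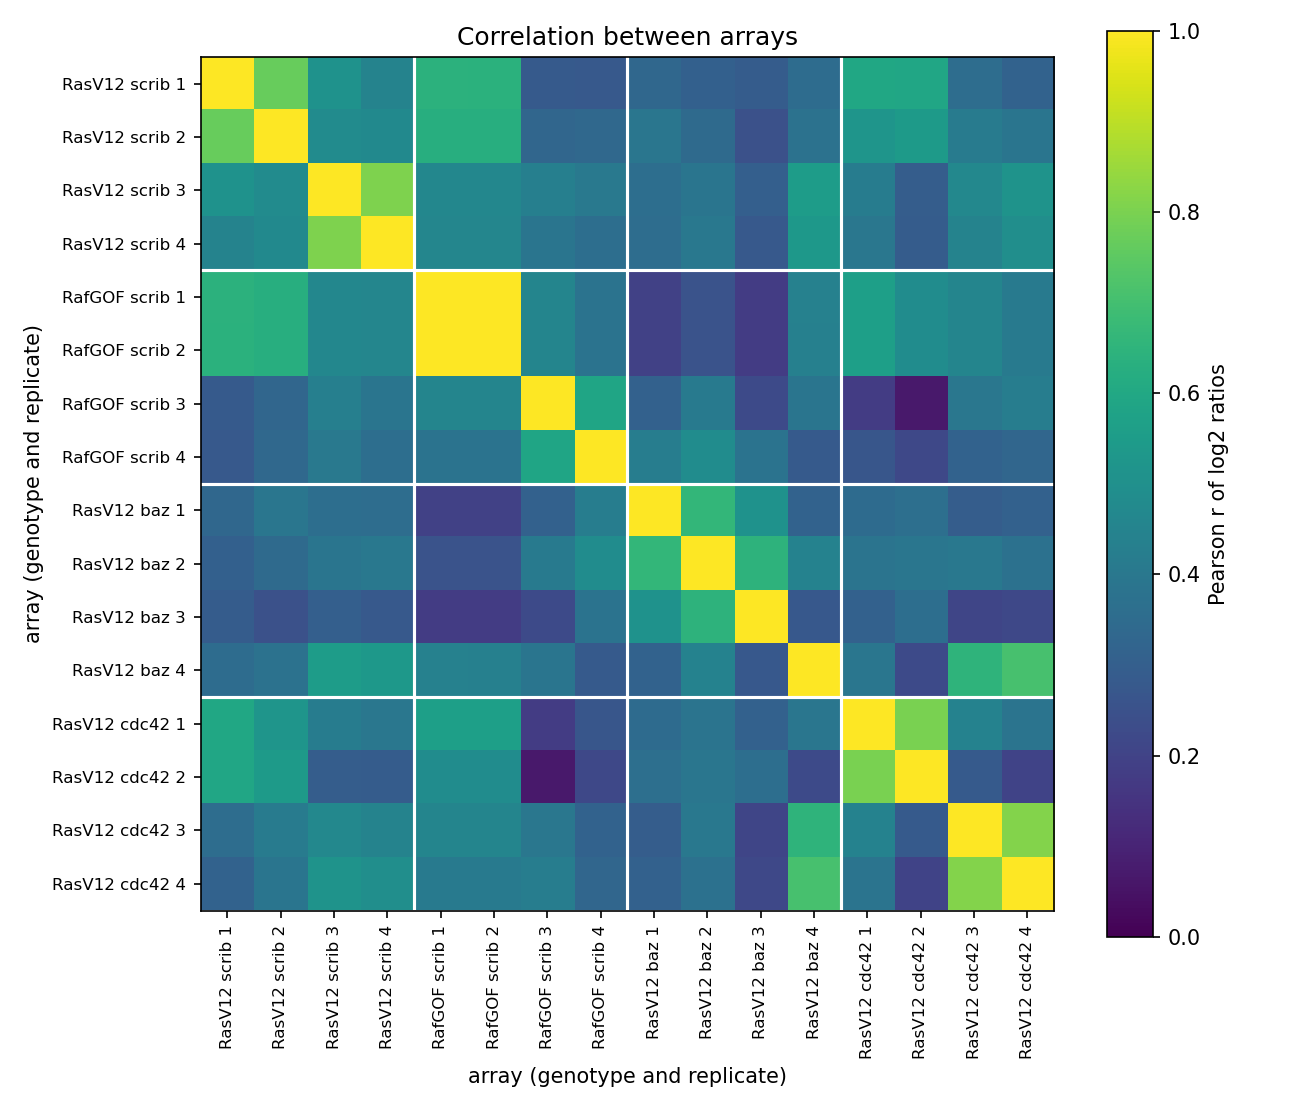
Pearson correlation of the log2 ratios (tumour over wild-type) between all 16 arrays, ordered by genotype and replicate on both axes, with colour from 0 to 1 and white lines between genotypes. RafGOF scrib replicates 1 and 2 form 1 block, and RasV12 baz replicate 4 lies nearest RasV12 cdc42 replicate 4 (r = 0.71).

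Gene symbols could be given to 71 of the 11196 features, so the named genes below are a small part of each result, and other features appear under their identifier. In RasV12 scrib tumours 2469 genes differed from wild-type, 1160 higher and 1309 lower (limma, Benjamini-Hochberg adjusted p under 0.05, n = 4). Of the 71 named genes 5 rose and 11 fell. The largest change among the named genes, in this reading a fall, was that of Lsp2, a larval serum protein made by the fat body, at a log2 value of -3.92 ± 0.64 (SE, adjusted p = 0.000143), or 15.1-fold. Eig71Ee, an ecdysone-induced gene, fell to -2.19 ± 0.33 (adjusted p = 6.33e-05) and Ebp, an ejaculatory bulb protein gene, to -1.21 ± 0.22 (adjusted p = 0.000409). CG12520 rose by 1.97 ± 0.23 on the log2 scale (adjusted p = 3.37e-06) and Treh, which encodes the trehalose-splitting enzyme trehalase, by 1.24 ± 0.26 (adjusted p = 0.00158). These 5 genes had the same sign on each of the 4 arrays, and none of the 28 settings each gene was refitted under ended its call. Of these settings 15 left out 1 replicate each. Leaving out an array of another genotype did not change a RasV12 scrib value against wild-type, only its error, so such refits are weaker checks.

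Smaller falls were measured in RasV12 scrib for Sec24CD, a subunit of the COPII vesicle coat (-0.81), for lwr, which encodes the SUMO-conjugating enzyme (-0.70), and for Ant2, a mitochondrial adenine nucleotide carrier (-0.70). CG15282 (-0.68), the chitinase-like Idgf3 (-0.63) and betaTub85D, a tubulin known from the testis (-0.60), also fell. CG5681 rose by 1.32 and the cohesin-loading gene Mau2 by 0.71. These 8 had the same sign on every RasV12 scrib array. Their calls were lost in 1 (Sec24CD), 2 (CG5681), 6 (Mau2), 9 (CG15282), 10 (lwr), 10 (Ant2), 11 (Idgf3) and 18 (betaTub85D) of 28 settings. CG41099 (0.93), AMPKalpha (-0.87) and Mst98Ca (-0.80) passed the threshold although at least 1 array had the opposite sign, and their calls were lost in 19 (CG41099), 7 (AMPKalpha) and 8 (Mst98Ca) of 28 settings. Centring was among those that ended the call of CG41099 (adjusted p = 0.0586). Among unnamed features, FBgn0001258 rose 44.3-fold and FBgn0022073 20.4-fold, and FBgn0001254 fell 55.1-fold and FBgn0024294 40.2-fold. With quantile normalization the split was 1519 higher and 592 lower, and with centred arrays it was 1212 and 1716. It was 1069 and 779 without replicate 1 and 866 and 1651 without replicate 3, so which direction had more genes stays open. With replicates 1-2 and 3-4 of each genotype as random blocks, a fit added after the data were seen, the count was 1131, and from the arrays with tumour RNA in Cy3 it was 1210.

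In RafGOF scrib tumours 531 genes differed from wild-type, 409 higher and 122 lower (n = 3). Of the 71 named genes only Ts, which encodes thymidylate synthase, passed the threshold, and it rose by 1.24 ± 0.26 on the log2 scale (2.37-fold, adjusted p = 0.00746) with all 3 replicates above 0. Its call was kept under all 28 settings. FBgn0033592 rose 15.7-fold and FBgn0001230 11.8-fold, and FBgn0001254 fell 20.4-fold and FBgn0034462 12.4-fold. These folds include the dye correction of the fit, which may hold a difference between replicate pairs of RasV12 cdc42. On the log2 scale the replicate means were 4.07, 2.59, -4.28 and -3.39 in that order. The fitted values were 3.98, 3.56, -4.35 and -3.63. A fit without the dye term gave 1016 genes, 883 higher and 133 lower. With each array centred on its median, 227 genes were higher and 237 lower. The count depended on the duplicated arrays: it was 158 without replicate 1 (the merged pair), 1540 with the pair kept as separate replicates and 273 with the random blocks. Array weights gave 1811.

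In RasV12 baz tumours 532 genes differed from wild-type, 409 higher and 123 lower (n = 4). Of the 71 named genes 4 rose and none fell. Swim, a secreted protein that binds the growth factor Wingless, rose by 2.28 ± 0.28 on the log2 scale (4.85-fold, adjusted p = 3.55e-05) and CG12520 by 1.56 ± 0.28 (adjusted p = 0.00189). Ts rose by 0.86 ± 0.23 (adjusted p = 0.0371) and CG12091 by 0.75 ± 0.21 (adjusted p = 0.0428), and centring ended both of these calls (adjusted p = 0.0820 and 0.0539). The call of Ts was lost in 12 of 28 settings, that of CG12091 in 15 and that of CG12520 in 1. All 4 genes were above 0 on each of the 4 arrays. FBgn0035193 rose 33.2-fold and FBgn0035049 19.1-fold, and FBgn0001254 fell 37.6-fold and FBgn0024294 9.34-fold. These folds include the dye correction of the fit, which may hold a difference between replicate pairs of RasV12 cdc42. On the log2 scale the replicate means were 5.00, 4.22, -5.16 and -2.71 in that order. The fitted values were 5.05, 4.25, -5.23 and -3.22. A fit without the dye term gave 983 genes, 842 higher and 141 lower. With centred arrays 337 genes were higher and 185 lower. The count was 259 without replicate 1, 241 without replicate 2, 352 without RasV12 cdc42 replicate 3 and 175 with the random blocks. It was 1509 with quantile normalization and 4726 with array weights.

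In RasV12 cdc42 tumours 911 genes differed from wild-type, 640 higher and 271 lower (n = 4). Of the 71 named genes 2 rose and none fell. Swim rose by 0.75 ± 0.23 on the log2 scale (adjusted p = 0.0470) and Idgf3 by 0.67 ± 0.19 (adjusted p = 0.0354), each above 0 on all 4 arrays. The call was lost in 12 of 28 settings for Swim and in 6 for Idgf3. FBgn0036690 rose 28.8-fold and FBgn0033592 26.4-fold, and FBgn0034462 fell 5.62-fold and FBgn0024294 5.53-fold. With centred arrays 501 genes were higher and 496 lower. The count was 500, 473, 466 and 538 without replicates 1, 2, 3 and 4 in turn, and 269 with the random blocks. It was 1758 with quantile normalization, 2252 with replicates 1-2 and 3-4 as a fixed block, 3213 from the RasV12 cdc42 arrays alone and 4067 with array weights. On those arrays alone the dye term coincides with replicates 1-2 against 3-4 and takes that difference out of the error.

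**Figure D2:**
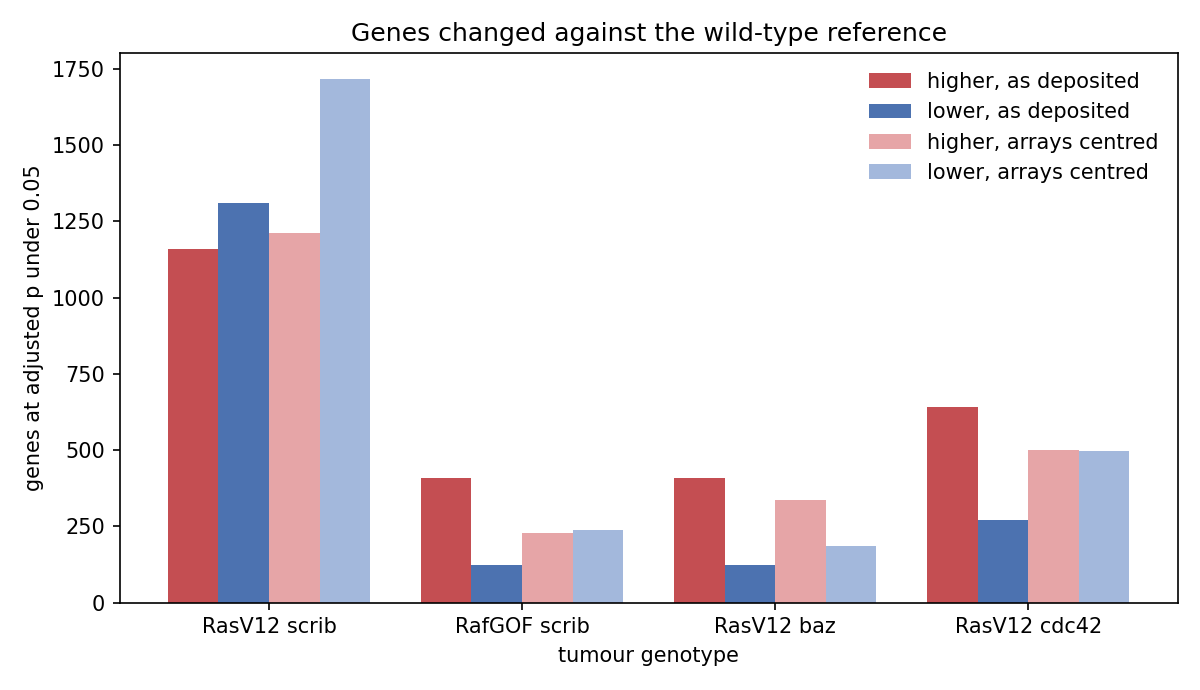
Number of genes at adjusted p under 0.05 against the wild-type reference (y axis) for each tumour genotype (x axis), split into higher and lower, for the values as deposited and for arrays centred on their median. RasV12 scrib has 1160 higher and 1309 lower genes as deposited, and centring moves RafGOF scrib from 409 higher and 122 lower to 227 and 237.

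The wild-type RNA entered these tests only as the reference. Where arrays share 1 reference RNA, its own spread is left out. In 20 simulations of unchanged tumours, a reference that did not vary gave on average 0 genes in RasV12 scrib. A single reference RNA that varied as much as a tumour array gave on average 2649 genes, 461 of them at least 2-fold and 15.5 at least 4-fold. The observed counts were 2469, 1003 and 194. The labels do not say whether 1 reference RNA served all arrays.

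In all 4 genotypes 126 genes changed the same way against wild-type, 84 higher and 42 lower, and none of them was among the 71 named genes. FBgn0033592 had the highest mean log2 change of the higher genes (4.01) and FBgn0035049 followed (3.79), while FBgn0001254 (-4.38) and FBgn0024294 (-3.57) were the lowest. With centred arrays 125 genes were shared, 56 higher and 69 lower, and 97 of these were among the 126. Independent lists of these sizes would share 0.0885 higher and 0.00379 lower genes. With a constant reference the simulated unchanged tumours had on average 0 genes called in RasV12 scrib, so they could share none. With a single reference that varied they shared 457 on average, and at a 2-fold limit 99.4 against 98 observed. The simulated tumour errors were independent between arrays, whereas real replicates 1-2 and 3-4 resembled each other. Pairwise correlations of the changes had a median r of 0.60 across genes (covariance 0.147), against 0.76 (covariance 0.189) with a varying reference and 0.00285 with a constant one. Part of the sharing may come from a common reference, which could not be split here. The age difference between tumours and reference discs was also common to all 4 genotypes. It cannot be told apart from the tumour in these shared genes. The count was 73 without RafGOF scrib replicate 1, 46 with the random blocks and 354 with array weights.

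Comparisons between genotypes do not rest on the level of the reference where it was the same. Among the 4 genotypes 445 genes differed (limma F-test, adjusted p under 0.05). The count was 193 on the arrays with tumour RNA in Cy3, 669 without RasV12 baz replicate 4, 64 with the random blocks and 1196 with array weights.

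RafGOF scrib and RasV12 scrib share the scrib loss and differ in the oncogene. Between them 132 genes differed, 91 higher and 41 lower in RafGOF scrib (n = 3 against 4). Ts was higher in RafGOF scrib by 1.61 ± 0.32 on the log2 scale (3.05-fold, adjusted p = 0.0159), and CG12520 was lower (-1.91 ± 0.39, 3.77-fold, adjusted p = 0.0171). No replicate of one genotype overlapped the other for either gene, and each of these 2 calls was lost in 8 of 28 settings. FBgn0000071 was 7.77-fold and FBgn0037000 7.17-fold higher in RafGOF scrib, and FBgn0003205 was 14.0-fold lower. FBgn0022073 was 15.9-fold lower, but centring ended its call (adjusted p = 0.0515), which was lost in 11 of 28 settings. The split was 70 higher and 71 lower with centred arrays, 42 and 58 with quantile normalization and 27 and 4 with equal spread on all arrays. The count fell to 35 without RafGOF scrib replicate 4, to 46 without RafGOF scrib replicate 3, to 50 without RasV12 scrib replicate 4 and to 13 with the random blocks. It was 576 with array weights and 280 without the arrays in doubt, which are RasV12 baz replicate 4 and the merged RafGOF scrib pair.

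RasV12 baz and RasV12 scrib share the activated Ras and differ in the polarity gene. Between them 338 genes differed, 276 higher and 62 lower in RasV12 baz (n = 4 each). Swim was higher in RasV12 baz by 2.33 ± 0.36 on the log2 scale (5.02-fold, adjusted p = 0.00154), Ts by 1.23 ± 0.30 (adjusted p = 0.0319) and CG12091 by 1.21 ± 0.27 (adjusted p = 0.0189), with no overlap between the arrays of the genotypes. The call of Swim was lost in 1 of 28 settings, that of Ts in 12 and that of CG12091 in 8. AMPKalpha (1.44, adjusted p = 0.0473) and Lsp2 (3.99 ± 1.01, adjusted p = 0.0373) were also higher, with overlapping arrays, and centring ended both calls, which were lost in 21 (AMPKalpha) and 18 (Lsp2) of 28 settings. FBgn0035193 was 30.7-fold and FBgn0000071 13.3-fold higher, and FBgn0036606 was 14.1-fold and FBgn0033395 9.91-fold lower. The split was 258 higher and 106 lower with centred arrays, 107 and 55 with quantile normalization and 56 and 4 with equal spread on all arrays. The count was 649 without RasV12 baz replicate 4, 128 without RasV12 baz replicate 2, 27 with the random blocks and 1411 with array weights.

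Between RasV12 cdc42 and RasV12 scrib 393 genes differed, 296 higher and 97 lower in RasV12 cdc42 (n = 4 each). Idgf3, which fell in RasV12 scrib and rose in RasV12 cdc42 against wild-type, differed between them by 1.30 ± 0.27 on the log2 scale (2.46-fold, adjusted p = 0.00830). Eig71Ee was higher in RasV12 cdc42 by 2.13 ± 0.46 (adjusted p = 0.0108) and Ebp by 1.51 ± 0.31 (adjusted p = 0.00674), while CG12520 was lower (-1.63 ± 0.33, adjusted p = 0.00565). For all 4 genes the arrays of the genotypes did not overlap, and the calls were lost in 4 (Idgf3), 5 (Eig71Ee), 4 (Ebp) and 2 (CG12520) of 28 settings. FBgn0035193 was 23.5-fold and FBgn0000071 16.1-fold higher, and FBgn0034097 was 15.3-fold and FBgn0036606 11.9-fold lower. The split was 169 higher and 101 lower with quantile normalization and 97 and 14 with equal spread on all arrays. The count was 252, 228 and 227 without RasV12 cdc42 replicates 2, 3 and 4 in turn, and 52 with the random blocks.

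Between RasV12 cdc42 and RasV12 baz 4 genes differed (limma, adjusted p under 0.05, n = 4 each), and 632 had an unadjusted p under 0.05. None was among the 71 named genes. FBgn0001254 was higher in RasV12 cdc42 by 3.11 ± 0.42 on the log2 scale (adjusted p = 0.00607) and FBgn0038478 by 2.71 ± 0.42 (adjusted p = 0.0194). FBgn0034657 was lower (-1.89 ± 0.32, adjusted p = 0.0309) and so was FBgn0040340 (-1.53 ± 0.25, adjusted p = 0.0195). Their calls were lost in 6 (FBgn0001254), 7 (FBgn0038478), 11 (FBgn0034657) and 8 (FBgn0040340) of 28 settings. On simulated data with errors independent between arrays, this comparison recovered 15% of the genes changed by a log2 value of 1. It recovered 92% of those changed by 2, and both may be too favourable for the real arrays. The split was 14 higher and 32 lower with quantile normalization and 3 and 7 with equal spread on all arrays. The count was 37 without RasV12 baz replicate 4, 116 without that array and the merged RafGOF scrib pair, and 0 without RasV12 cdc42 replicate 4. The random blocks and the replicate block each left 0 genes, and array weights gave 2836 (767 higher and 2069 lower), so the number of differences stays open.

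RasV12 scrib differed in the same direction from each of the other 3 genotypes for 51 genes, 9 of them higher and 42 lower in RasV12 scrib. This count was 3 with equal spread on all arrays, 3 with the random blocks, 8 with quantile normalization and 13 without RafGOF scrib replicate 4, and 153 with array weights. Independent lists of the sizes found would share 0.00197 and 0.0593 genes, which leaves out the RasV12 scrib arrays common to the 3 comparisons. The simulated unchanged tumours shared 0 at most, but they held no difference between genotypes, so that value sets no level for the real overlap. Part of the overlap may come from the common RasV12 scrib arrays. Of the named genes, CG12520 was higher in RasV12 scrib than in RafGOF scrib and RasV12 cdc42, and its difference from RasV12 baz was not significant (-0.40 ± 0.37, adjusted p = 0.671).

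**Figure D3:**
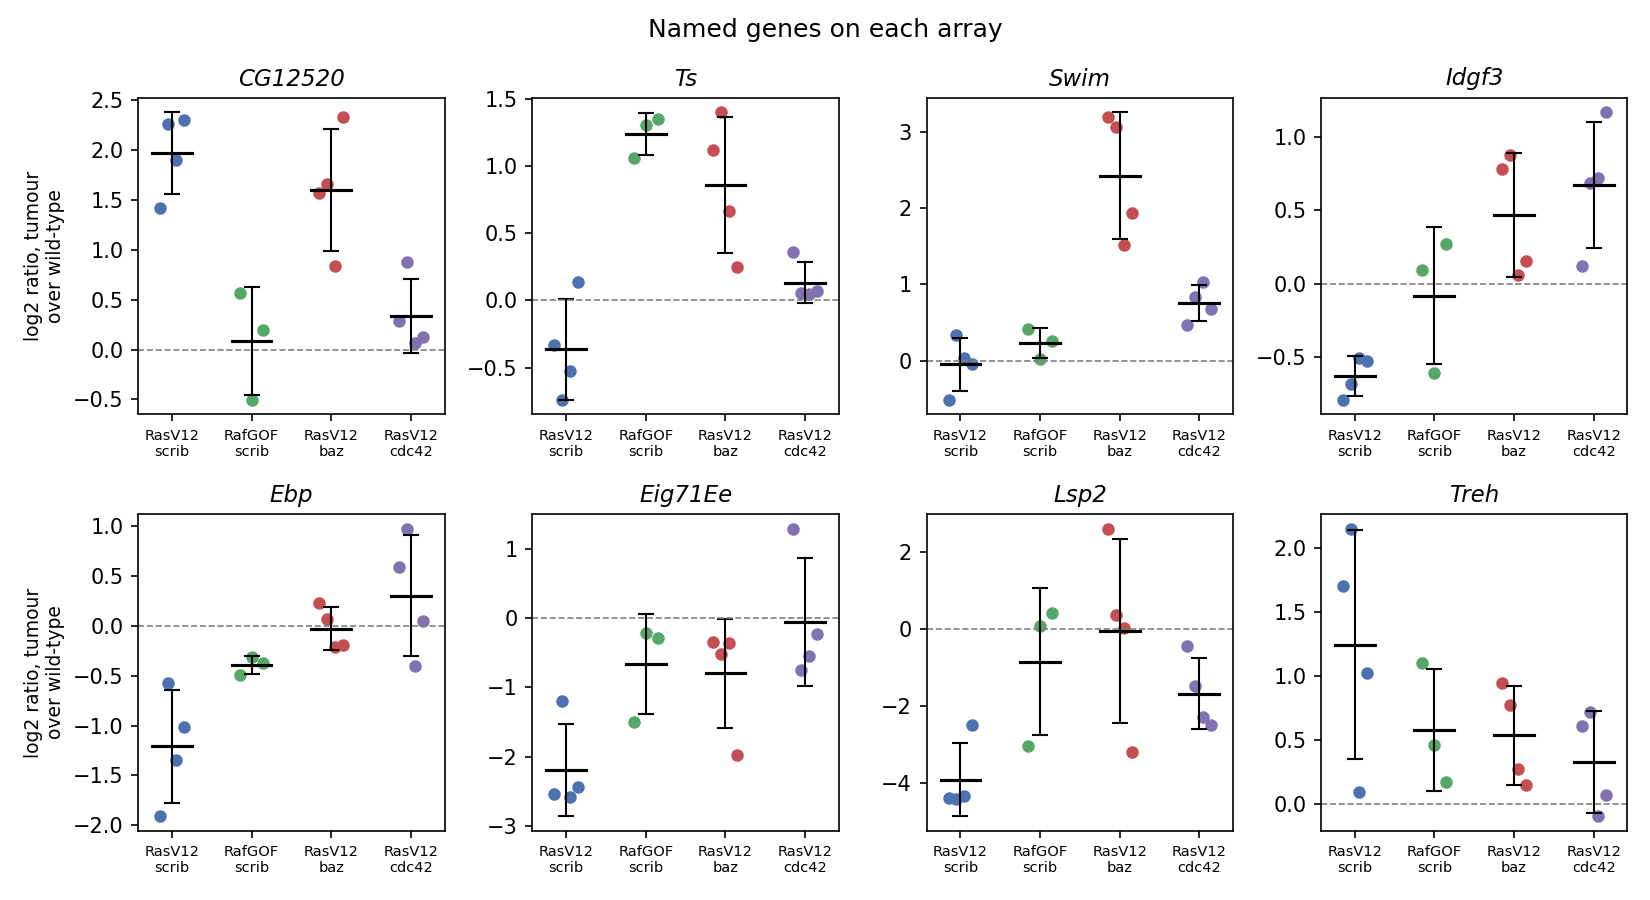
Log2 ratio of tumour over wild-type (y axis) for 8 named genes on each replicate, by tumour genotype (x axis). Dots are replicates (n = 4, and n = 3 for RafGOF scrib with its duplicated arrays averaged), black lines are means and bars are 1 SD. Idgf3 lies below 0 on all 4 RasV12 scrib arrays and above 0 on all 4 RasV12 cdc42 arrays.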

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

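Tests chosen only after the result was seen were those of a wrong label and of a shared batch for RasV12 baz replicate 4, of dye orientation and of shared tumour RNA for the replicate pairs, of array number for the RasV12 scrib count, and the splits that respect the replicate numbers. The others were written before their result was seen.

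Replicates stood apart from the rest of their genotype in 4 of the 51 groups tested (named genes and array medians in the genotypes with 4 replicates), where chance gives about 2.55. Lsp2 was at -2.49 on RasV12 scrib replicate 4 and between -4.44 and -4.36 on the other arrays of the genotype. Eig71Ee was at -1.19 on RasV12 scrib replicate 2 and between -2.58 and -2.44 on the others, and at -1.98 on RasV12 baz replicate 4 and between -0.51 and -0.34 on the others. Ts was at 0.36 on RasV12 cdc42 replicate 1 and between 0.05 and 0.07 on the others.

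Differences between genotypes that passed their own test were 132 genes for RafGOF scrib against RasV12 scrib, 338 for RasV12 baz against RasV12 scrib, 393 for RasV12 cdc42 against RasV12 scrib, 4 for RasV12 cdc42 against RasV12 baz and 445 among the 4 genotypes. The named genes among them were Ts (1.61) and CG12520 (-1.91) for RafGOF scrib against RasV12 scrib. They were Swim (2.33), Ts (1.23) and CG12091 (1.21) for RasV12 baz against RasV12 scrib, and with overlapping arrays also AMPKalpha (1.44) and Lsp2 (3.99). For RasV12 cdc42 against RasV12 scrib they were Eig71Ee (2.13), Ebp (1.51), Idgf3 (1.30) and CG12520 (-1.63).

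Other splits of the same arrays were counted for these comparisons. For RasV12 baz against RasV12 scrib 1 of 35 splits, the real one, gave 338 genes and the highest other gave 64, so chance was excluded at a share of 0.05 only if arrays can be exchanged freely. With 2 replicates of each number group (1-2 and 3-4) on each side there are 18 splits, too few for that share, and the random blocks left 27 genes. For the 4 genotypes 1 of 100 splits, the real one, gave 445 genes and the highest other gave 49, and with arrays exchanged within number groups it was again 1 of 100 (highest other 78). With whole pairs 1-2 and 3-4 exchanged between genotypes 12 of 105 splits gave as many genes (highest other 953), so chance was not excluded when replicates of a pair are kept together. The random blocks left 64 genes. For RafGOF scrib against RasV12 scrib 2 of 35 splits reached 132 genes, so chance was not excluded. The other one, with 350 genes, set replicate 1 of RafGOF scrib and replicates 1 and 2 of RasV12 scrib against replicates 3 and 4 of both. For RasV12 cdc42 against RasV12 scrib 2 of 35 splits reached 393 genes, so chance was not excluded. The other one, with 482 genes, set replicates 1 and 2 of both genotypes against replicates 3 and 4 of both. Both of these splits follow the replicate numbers, which points to a structure of the arrays beside the genotype. With replicates 1-2 and 3-4 as a fixed block the counts were 266 and 526, and with the random blocks they were 13 and 52. With 2 replicates of each number group on each side, 1 of 18 splits, the real one, gave 393 genes for RasV12 cdc42 against RasV12 scrib and the highest other gave 3, but 18 splits are too few for a share under 0.05. For RasV12 cdc42 against RasV12 baz 2 of 35 splits reached 4 genes, so chance was not excluded, and the highest other gave 26 genes with RasV12 baz replicate 4 on the side of RasV12 cdc42 replicates 1, 3 and 4. Of the 18 splits balanced for number groups, again too few, the highest other gave 0.

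The first pattern is the place of RasV12 baz replicate 4, which correlated with RasV12 cdc42 replicates 3 and 4 at 0.65 and 0.71 and with its own genotype at 0.28 to 0.44. On 113 genes that separated RasV12 baz replicates 1 to 3 from RasV12 cdc42, chosen without replicate 4, it lay at a median of 0.0744 on a scale from 0 (RasV12 cdc42) to 1 (RasV12 baz). Left-out RasV12 cdc42 arrays lay between -0.13 and 0.46 on this scale and left-out RasV12 baz arrays between 0.56 and 0.93, so a wrong label may account for the pattern. Single genes went both ways. Swim was at 1.93 on this array (0.47 to 1.03 on RasV12 cdc42 arrays, 1.52 to 3.19 on the other RasV12 baz arrays), against a wrong label. CG12520 at 2.32 (0.06 to 0.87 and 0.83 to 1.66) lay above the arrays of both genotypes, nearer RasV12 baz. Ts at 0.25 (0.05 to 0.36 and 0.67 to 1.40) lay on the side of RasV12 cdc42. Lsp2 at -3.22 (-2.49 to -0.46 and 0.03 to 2.60) lay below the arrays of both genotypes, nearer RasV12 cdc42. A wrong label stays open. A batch shared with replicates 3 and 4 of all 3 other genotypes also stays open: its deviation followed those replicates in 2 of the 3 genotypes and in RafGOF scrib ran the other way (mean r = -0.19 with replicates 3 and 4, and 0.28 with replicate 1), but by less than it followed them in RasV12 cdc42 (0.34 and -0.31). A biological difference of this tumour sample from the rest of its genotype is open and untested.

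The second pattern is the pairing of replicates 1-2 and 3-4 in RasV12 scrib and RasV12 cdc42. Dye orientation is argued against in RasV12 scrib, where same-dye pairs correlated less than the pairs 1-2 and 3-4 (difference of mean r -0.296), and as the whole cause in RasV12 cdc42. There dyes and numbers coincide, but the difference of RasV12 scrib arrays by dye followed the RasV12 cdc42 split over genes with a slope of 0.0635, where a dye effect common to both genotypes as the whole cause needs about 0.825. A contrast of RasV12 scrib arrays that follows neither dye nor number had a slope of 0.0743 and the number contrast 0.397. A part played by dye in RasV12 cdc42 stays open. A few extreme genes are argued against, since without the tenth of genes of largest variance the gap was at least 1.25 times that over all genes. Tumour RNA shared within a pair stays open as the whole cause. The RasV12 cdc42 split correlated with that of RasV12 scrib at 0.343 over genes, but also at 0.337 with a contrast of RasV12 baz arrays that does not follow the numbers. Another such RasV12 baz contrast gave -0.278, and both include replicate 4, an array in doubt. Such contrasts of RasV12 scrib gave 0.102 and 0.135. Deviations of RasV12 scrib and RasV12 cdc42 correlated at 0.01 to 0.35 within a number group and at -0.38 to -0.12 across groups (8 pairs each). Deviations sum to 0 within a genotype, so these pairs are not independent. A batch of larvae, reference RNA or hybridisations common to both genotypes is a candidate explanation that no label records, and no biological explanation was tested.

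The third pattern is the excess of genes changed against wild-type in RasV12 scrib, 2469 against at most 911 in another genotype. Its ranking depended on the fit. Array weights gave 1645 for RasV12 scrib, 1811 for RafGOF scrib, 4726 for RasV12 baz and 4067 for RasV12 cdc42. The compared genotypes alone gave 1389 for RasV12 scrib and 3213 for RasV12 cdc42, and the arrays with tumour RNA in Cy3 gave 1210 for RasV12 scrib and 1052 for RafGOF scrib. A smaller error from more arrays or balanced dyes is argued against in the fit of all arrays, where RasV12 cdc42 has as many arrays and swaps and RasV12 scrib had 2.71 times its count, but the other fits above leave the excess itself open. The wider spread of the RasV12 scrib log2 ratios may account for most of the excess, since with all arrays scaled to equal spread its count was 1.19 times the next highest. That scaling also shrinks real changes on arrays that hold many, so a larger response of RasV12 scrib tumours and a technical gain in these ratios both stay open.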

How the results depend on the processing

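The random blocks of replicates 1-2 and 3-4 and the fixed block of the same replicates were chosen after seeing the data. So were the RafGOF scrib pair kept as 2 replicates and the fit without the arrays in doubt. The other settings were fixed before, but the gene-by-gene estimate of array weights was taken after another did not converge. None of the refitted calls of named genes or printed identifiers reversed. The tallies that follow leave out the 5 named calls with overlapping arrays, which were refitted separately and did not reverse. Of the 261 refits of named genes under planned settings other than leave-one-out 188 kept the call and 73 lost it, of 116 under added settings 95 kept it, and of 435 with 1 replicate left out 364 kept it. For printed identifiers 269 of 288, 122 of 128 and 460 of 480 kept it. The calls of the 4 genes of RasV12 cdc42 against RasV12 baz were all lost under the replicate block and under the random blocks. Signal over background was not used here, so what it limits is unknown. The cause of the moves below was not tested, except that fewer arrays enter the fits on Cy3 arrays, on the compared genotypes and with arrays left out. Counts that stayed within 1.5 times of the reported count are not listed, and all counts stayed so with centring and with robust empirical Bayes.

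Without the dye term the count against wild-type was 1016 for RafGOF scrib and 983 for RasV12 baz; it was 366 for RafGOF scrib and 640 for RasV12 baz against RasV12 scrib, 14 for RasV12 cdc42 against RasV12 baz and 208 for all 4 genotypes alike. On arrays with tumour RNA in Cy3 it was 1210, 1052, 1024 and 524 against wild-type for RasV12 scrib, RafGOF scrib, RasV12 baz and RasV12 cdc42. There it was 165 and 129 for RasV12 baz and RasV12 cdc42 against RasV12 scrib, 2 for RasV12 cdc42 against RasV12 baz and 193 among genotypes. Scaling to equal spread gave 1283 for RasV12 scrib and 982 for RafGOF scrib against wild-type, 31, 60 and 111 for RafGOF scrib, RasV12 baz and RasV12 cdc42 against RasV12 scrib, 10 for RasV12 cdc42 against RasV12 baz and 266 among genotypes. Quantile normalization gave 1078, 1509 and 1758 for RafGOF scrib, RasV12 baz and RasV12 cdc42 against wild-type, 162 for RasV12 baz against RasV12 scrib, 46 for RasV12 cdc42 against RasV12 baz and 275 for all 4 alike.

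Array weights, estimated gene by gene, gave 1645, 1811, 4726 and 4067 against wild-type in the order above, 576 and 1411 for RafGOF scrib and RasV12 baz against RasV12 scrib, 2836 for RasV12 cdc42 against RasV12 baz, 1196 among genotypes and 354 for all 4 alike. The compared genotypes alone gave 1389, 845 and 3213 for RasV12 scrib, RasV12 baz and RasV12 cdc42 against wild-type, 18 and 36 for RafGOF scrib and RasV12 baz against RasV12 scrib and 2 for RasV12 cdc42 against RasV12 baz. At least 2-fold changes numbered 1003 for RasV12 scrib and 423 for RasV12 cdc42 against wild-type.

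Replicate numbers did not pair the samples throughout: 12 of 21 same-numbered pairs of deviations correlated over 0.1, the lowest at -0.35. Their mean was 0.10, against -0.03 for other pairs, and 7 of 15 replicates correlated best with their own number. Same-numbered pairs of RasV12 scrib lay at 0.21 to 0.28 with RasV12 cdc42 and at 0.13 to 0.28 with RafGOF scrib. Pairs of RasV12 scrib and RasV12 cdc42 with different numbers within 1-2 or 3-4 lay at 0.01 to 0.35. The replicate block, fitted with the dye term, gave 935 for RafGOF scrib and 502 for RasV12 cdc42 against wild-type, 55 and 204 for RafGOF scrib and RasV12 baz against RasV12 scrib and 0 for RasV12 cdc42 against RasV12 baz (limma; 632 genes at an unadjusted p under 0.05 without the block).

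The random blocks, with an estimated correlation of 0.566, gave 1131, 273, 175 and 269 against wild-type, 13, 27 and 52 for RafGOF scrib, RasV12 baz and RasV12 cdc42 against RasV12 scrib, 0 for RasV12 cdc42 against RasV12 baz, 64 among genotypes and 46 for all 4 alike. In the comparisons with wild-type and between pairs of genotypes, every one of these calls was also in the reported list, except 2 for RafGOF scrib against wild-type. The lists among genotypes and for all 4 alike were not compared in this way. Replicates 1-2 and 3-4 as a fixed block gave 1790, 1185 and 2252 for RafGOF scrib, RasV12 baz and RasV12 cdc42 against wild-type, 266 for RafGOF scrib against RasV12 scrib and 334 for all 4 alike. The RafGOF scrib pair kept separate gave 1540 against wild-type and 382 against RasV12 scrib. Without the arrays in doubt the counts were 187 for RafGOF scrib against wild-type, 280 and 780 for RafGOF scrib and RasV12 baz against RasV12 scrib, 116 for RasV12 cdc42 against RasV12 baz, 747 among genotypes and 75 for all 4 alike.

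With each of the 15 replicates left out in turn, counts against wild-type ranged from 1848 to 2580 for RasV12 scrib, 158 to 648 for RafGOF scrib, 241 to 624 for RasV12 baz and 466 to 1102 for RasV12 cdc42. Counts against RasV12 scrib ranged from 35 to 237 for RafGOF scrib, 128 to 649 for RasV12 baz and 227 to 451 for RasV12 cdc42. They ranged from 0 to 37 for RasV12 cdc42 against RasV12 baz, 297 to 669 among genotypes and 73 to 147 for all 4 alike. Beyond the values given with each comparison, RafGOF scrib against RasV12 scrib had 237 genes without RasV12 scrib replicate 3 and 234 without RasV12 baz replicate 4. RasV12 baz against RasV12 scrib had 158 and 171 without RasV12 scrib replicates 2 and 4, 162 without RasV12 baz replicate 1, and 201, 193 and 219 without RasV12 cdc42 replicates 1, 3 and 4. RasV12 cdc42 against RasV12 baz had 1 gene without RasV12 baz replicate 1, without RasV12 baz replicate 2 and without RasV12 cdc42 replicate 3, and 15 without RasV12 baz replicate 3.

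The count of genes in which RasV12 scrib differed alike from the other 3 genotypes was 51 as reported. It was 107 without the dye term, 27 on Cy3 arrays, 25 with the replicate block, 3 with the compared genotypes alone, 94 with the fixed block, 85 with the RafGOF scrib pair separate and 108 without the arrays in doubt, and 13 to 84 with 1 replicate left out.

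Not run were filters on missing values and rules for several probes of a gene, which change nothing in this table, and tests of the gene lists and engineered genes, too few of which were matched to identifiers.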

Other observations

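Lsp2, the only matched fat body marker among the fixed lists, varied more between RasV12 baz arrays than between RasV12 scrib arrays, with values of 2.60, 0.36, 0.03 and -3.22 on RasV12 baz replicates 1 to 4. On RasV12 scrib replicates 1 to 4 it was at -4.40, -4.44, -4.36 and -2.49. The RasV12 baz mean of -0.05 (SD 2.40, n = 4) rests on replicate 4, an array in doubt, and the other 3 replicates were all above 0 (SD 1.40). The fitted log2 change was 0.07 in RasV12 baz, -1.69 in RasV12 cdc42 and -0.73 in RafGOF scrib, and none of these 3 passed the test against wild-type (limma adjusted p = 0.977, 0.123 and 0.662). The laminin gene LanA, the only matched basement membrane gene, was at -0.20 in RasV12 scrib, 0.10 in RafGOF scrib, 0.08 in RasV12 baz and 0.13 in RasV12 cdc42, and passed no test (adjusted p = 0.574, 0.863, 0.920 and 0.779).

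FBgn0001254 fell in all 4 genotypes and fell less in RasV12 cdc42 (-2.13 ± 0.27 SE) than in RasV12 baz (-5.23 ± 0.33), a difference that passed its own test (adjusted p = 0.00607) but was lost in 6 of 28 settings, among them the random blocks and the replicate block. Fold changes taken from replicates 1-2 alone and from replicates 3-4 alone had the same sign for 99.5% of the 2469 genes called in RasV12 scrib and for each of the 393 genes called between RasV12 cdc42 and RasV12 scrib, although these genes were chosen on all replicates. Over all genes the sign was the same for 58.2% and 50.0% (r = 0.53 and 0.21 across genes).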
